A study of Arabidopsis thaliana with 12 samples.

How the data were processed

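Whole-seedling RNA of Arabidopsis thaliana was sequenced in 12 libraries, 3 for each combination of genotype (wild type No-0 or 35S::KNAT1) and medium (PAC or PAC+GA3). The labels' protocols name both an RNeasy and a Trizol extraction, and both a TruSeq RNA and a TruSeq Stranded mRNA kit, so it is not certain which of them applied. The authors deposited raw read counts per gene in 1 table, with 1 column per library and no pooling. Per the submitters' processing notes, the TAIR10 build was used with cutadapt 1.8.3, FastQC 0.11.5, TopHat2 2.1, DESeq2 1.16.1 and edgeR 3.0.2, listed without roles. The counting tool and its strand setting are not given in the sources used here. Without a known strand setting, reads of overlapping and antisense genes cannot be told apart, and how reads shared by near-identical genes were counted is unknown.

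The count table held 32673 genes, of which 9247 had no count in any library. The locus of 31900 was found in the reference gene table, and 31877 of these also overlapped its position. In 24 rows the locus was blank or shared with another row and was set from the coordinates. Groups and replicate numbers came from the sample labels. Replicates of a group were compared by a chi-square of their counts over genes, which lay between 3.87 and 15.65 per degree of freedom, so no pair looked like copies of a single library.

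Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr (minimum count 10), which kept 19879, libraries were scaled by TMM, and 1 quasi-likelihood model with robust dispersions and 4 group means was fitted to all 12 libraries. The common biological coefficient of variation was 10.3%. Contrasts gave the GA effect in each genotype, the genotype effect in each medium and their interaction. Genes were called at a Benjamini-Hochberg adjusted p below 0.05 over all genes tested. SEs are the log2 change divided by the square root of its F value, and 95% intervals of the interaction used 8 degrees of freedom. CPM values are TMM-scaled, with the SD over 3 replicates.

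In total 21 gene lists were fixed before the data were examined: GA feedback, GA catabolism, GA early synthesis and DELLA genes, class I KNOX, BELL and boundary genes, secondary wall cellulose, secondary wall xylan, lignin synthesis, secondary wall transcription factors, vessel cell death, expansins and XTHs, growth bHLH factors, auxin response, brassinosteroid metabolism, cytokinin, cell cycle, flavonoid synthesis, jasmonate and wounding, salicylate defence, low-oxygen response, green tissue markers, and root hair and root markers. Each was tested with camera in limma 3.58.1 on voom values, two-sided, with a preset inter-gene correlation of 0.01 and with an estimated one, and adjusted over 105 list tests. With the estimated correlation, 0 lists were called in any comparison. This loss does not reflect correlation between genes alone. For GA catabolism the estimate lay below the preset, at -0.054 for the GA effect in wild type and -0.065 in 35S::KNAT1. Its unadjusted camera p still rose, from 0.000187 to 0.00529 and from 2.87e-08 to 0.000491. Camera sets a list against the other genes. Fry, which sets a list against no change, was run beside it.

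Named genes followed a rule fixed before the data were examined. It took KNAT1, up to 4 members per list with the smallest p in a comparison, any member of the KNOX, GA feedback and secondary wall transcription factor lists, and the 6 largest rises and 6 largest falls. These last had to be called, have a symbol, reach a mean of 1 CPM in a group compared and show no overlap between the groups' libraries. With 3 libraries against 3, chance alone gives no overlap in 10% of genes.

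Libraries of the same replicate number deviated together from their group means. The correlations of these deviations were 0.359, 0.170 and 0.288 between wild-type PAC and PAC+GA3, 0.169, 0.120 and 0.203 between the 35S::KNAT1 groups, and 0.250, 0.220 and 0.103 between genotypes under PAC. Between genotypes under PAC+GA3 they were 0.134, -0.029 and 0.079, so the numbers were not taken to pair those. Across both factors they were -0.037, -0.062 and 0.054 between wild-type PAC and 35S::KNAT1 PAC+GA3, and 0.143, 0.002 and 0.062 between wild-type PAC+GA3 and 35S::KNAT1 PAC. The labels themselves state no pairing. Their titles give all libraries of a number the same letter (A, B or C), with no meaning stated. The replicate block spanned all 12 libraries, so it gave each number 1 shift shared by all groups, which these values support only in part. It is given beside results of the 3 paired comparisons where it changes a call by camera or moves a count of calls by over 1.5 times. For genotype under PAC+GA3 and the interaction it is given apart, as an alternative only.

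The alternatives were DESeq2 size factors, total-count scaling, no filter, a stricter filter (5 CPM in 3 libraries), the DESeq2 1.42.0 Wald test, a fit of only the groups compared, the replicate block and leaving out each library. A replicate block within each genotype, removal of rRNA and organelle genes, and removal of 3 libraries with a high rRNA share were added after the data had been seen. The model was tested on simulated counts. For the GA effect in wild type (19680 genes), it recovered 71.2% of genes changed 1.5-fold, 92.5% of those changed 2-fold and 95.5% of those changed 4-fold, all at a mean of at least 5 CPM, with 13 false calls. For the genotype effect under PAC (19684 genes) it recovered 66.7%, 89.6% and 98.5%, with 5 false calls. For the interaction (19678 genes) it recovered 30.3%, 74.6% and 98.5%, with 11 false calls. The simulated libraries were independent, with no shifts shared by a replicate number and no rRNA or organelle shifts. These shares therefore do not measure recovery in the real libraries.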

Results

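RNA was measured by sequencing in whole seedlings of Arabidopsis thaliana of the Nossen accession (No-0). The 12 libraries formed 4 groups of 3 replicates: wild type and a line that expresses KNAT1 from the 35S promoter (35S::KNAT1), each in paclobutrazol alone (PAC) or in paclobutrazol with gibberellin (PAC+GA3). KNAT1 is a class I KNOX homeodomain transcription factor, and paclobutrazol blocks gibberellin (GA) synthesis. Seedlings 7 days old were kept in 10 µM PAC for 18 h and then for 5 h in 10 µM PAC with or without 100 µM GA3. Total counts per library ran from 9232836 to 14053594, and 19879 genes passed the filter on low counts. The labels do not say whether replicates came from separate cultures, so the p-values measure the spread between these samples, which may be technical. An rRNA gene, AT3G41768, took 0.488% and 0.347% of counts in wild-type PAC replicates 2 and 3 and 1.435% in 35S::KNAT1 PAC+GA3 replicate 1. In the other 9 libraries it took between 0.11% and 0.197%. Organelle genes took 0.944%, 0.676% and 0.868% of counts in those 3 libraries and between 0.139% and 0.263% in the rest.

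The overexpressed gene was examined first, because it checks the labels. KNAT1 (AT4G08150, chromosome 4, 5147700 to 5150966, TAIR10) stood at 20.7 ± 3.55 CPM (SD, n = 3) in wild type under PAC and 22.2 ± 0.459 CPM (SD, n = 3) under PAC+GA3. In 35S::KNAT1 it stood at 423 ± 30.8 CPM (SD, n = 3) and 437 ± 42.2 CPM (SD, n = 3). The log2 difference between genotypes was 4.36 ± 0.12 (SE) under PAC and 4.30 ± 0.12 (SE) under PAC+GA3, and every 35S::KNAT1 library lay above every wild-type library. GA3 gave log2 differences of 0.10 ± 0.12 (SE) in wild type and 0.05 ± 0.10 (SE) in 35S::KNAT1, neither called by the edgeR quasi-likelihood test.

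**Figure D1:**
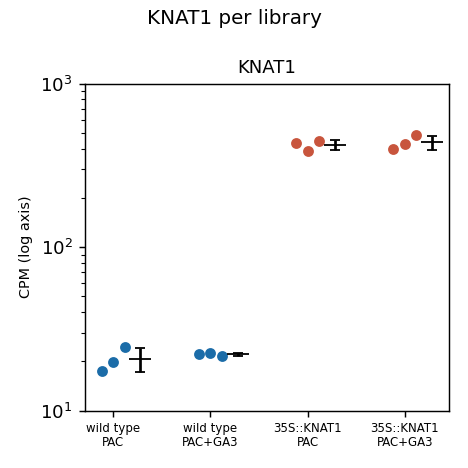
KNAT1 level in CPM (log axis) in each of the 12 libraries, by group; points are libraries, and the bar beside them is the mean with its SD (n = 3). Wild-type group means lie at 20.7 and 22.2 CPM and 35S::KNAT1 group means at 423 and 437 CPM.

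The first comparison asked what 5 h of GA3 changed in wild-type seedlings held in PAC. Of the genes fixed as repressed by GA through feedback, 3 fell. GA20OX2, a GA 20-oxidase of late GA synthesis (AT5G51810, chromosome 5, 21055188 to 21056808), went from 6.56 ± 2.76 to 0.882 ± 0.187 CPM (SD, n = 3), a log2 change of -2.88 ± 0.40 (SE). GA3OX1, a GA 3-oxidase (AT1G15550, chromosome 1, 5344478 to 5346166), went from 8.64 ± 1.42 to 1.90 ± 0.607 CPM (SD, n = 3), a log2 change of -2.15 ± 0.26 (SE). SCL3, a GRAS regulator of GA responses (AT1G50420), changed by -1.01 ± 0.13 (SE). The calcium/proton exchanger gene CAX1 changed by -0.60 ± 0.09, and the tyrosine decarboxylase gene TYRDC and RCI2B rose by 0.99 ± 0.17 and 0.60 ± 0.08 on the log2 scale (SE).

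In all, 3 genes were higher and 6 lower after GA3 in wild type at an edgeR Benjamini-Hochberg adjusted p below 0.05. Of the 12 tested members of the GA feedback list, 3 fell and 9 did not pass. Adjusted over the list alone, 8 fell, and the list stood apart as lower (camera adjusted p = 5.39e-10; adjusted p = 0.139 with an estimated correlation). None of the 4 tested GA catabolism genes passed, 2 were higher adjusted over the list alone, and camera placed the list higher (adjusted p = 0.00178; adjusted p = 0.139 with an estimated correlation). Expansins and XTHs, which loosen or remodel cell walls, had 0 of 23 members called, 5 higher adjusted over the list alone, and a camera call as higher (adjusted p = 0.000495; adjusted p = 0.178 with an estimated correlation). EXPA1 stood 0.69 ± 0.12 (SE) higher on the log2 scale and EXPA2 3.25 ± 0.53 (SE) higher, at adjusted p of 0.0549 and 0.0599. The auxin response list had 0 of 21 members called and 1 higher adjusted over the list alone, with a camera call as higher (adjusted p = 1.94e-05; adjusted p = 0.584 with an estimated correlation). Flavonoid and anthocyanin genes had 0 of 7 called and 5 lower adjusted over the list alone, and camera placed them lower (adjusted p = 2.31e-06; adjusted p = 0.359 with an estimated correlation). Their anthocyanin members LDOX and DFR stood at -1.79 ± 0.32 and -2.0 ± 0.38 (SE) on the log2 scale, at adjusted p of 0.0535 and 0.0730. No member of the secondary wall cellulose, xylan or transcription factor lists or of the lignin list passed in wild type over all genes tested, and adjusted over the list alone 1 transcription factor was higher. Organelle genes had a median log2 change of -1.62 in this comparison, with 0 of 102 called.

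The number of genes called for GA3 in wild type depended on the model. With the replicate number as a block it was 94 (49 higher, 45 lower), which includes all 9 genes. With the block within genotype, a fit chosen after the data were seen, it was 238 (124 higher, 114 lower), and in only the groups compared it was 2 (0 higher, 2 lower). Under the block over all groups 5 GA feedback genes fell, with GID1A and GID1B added, 6 expansins or XTHs rose, EXPA1 and EXPA2 among them, 3 flavonoid genes, LDOX, DFR and FLS1, fell, and the DELLA genes GAI and RGL1 rose. DESeq2 called 43 genes. Leaving out wild-type PAC replicate 1 gave 16 genes and replicate 2 gave 5, wild-type PAC+GA3 replicate 1 gave 3 and replicate 3 gave 4, and 35S::KNAT1 PAC+GA3 replicate 3 gave 4. Without the 3 libraries of high rRNA share, which leaves wild-type PAC with 1 library assumed to vary like the others, edgeR called 0 genes, with 1104 at an unadjusted p below 0.05, and DESeq2 was not run. Of 22 alternatives, TYRDC was not called in 12, GA20OX2 and CAX1 in 7 each, RCI2B in 3, and GA3OX1 and SCL3 in 1 each.

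The same treatment was examined in 35S::KNAT1. GA20OX2 changed by -2.91 ± 0.39 and GA3OX1 by -2.25 ± 0.28 (SE) on the log2 scale, SCL3 by -0.98 ± 0.13 and the GA receptor gene GID1A by -0.58 ± 0.09. GASA5, a GA-regulated gene of the GASA family, changed by -1.47 ± 0.26, the cellulose synthase-like gene CSLB03 by -1.43 ± 0.22 and the cytochrome P450 gene CYP96A12 by -0.93 ± 0.12 (SE). CYP78A5, a cytochrome P450 that promotes organ growth, rose from 6.15 ± 0.781 to 12.3 ± 1.24 CPM (SD, n = 3), a log2 change of 0.98 ± 0.18 (SE). The desaturase gene ADS1(AT1G06080) and the arabinogalactan protein gene AGP4 rose by 0.84 ± 0.15 and 0.56 ± 0.10.

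Here 3 genes were higher and 19 lower at an edgeR adjusted p below 0.05. The GA feedback list had 4 of 12 members lower, 8 adjusted over the list alone, and a camera call as lower (adjusted p = 7.21e-15; adjusted p = 0.0598 with an estimated correlation). All 4 tested GA catabolism genes were higher adjusted over the list alone, 0 over all genes, and camera placed them higher (adjusted p = 1.01e-06; adjusted p = 0.0515 with an estimated correlation). Camera also placed expansins and XTHs higher (0 of 23 called, 1 over the list alone; adjusted p = 0.0133, and adjusted p = 0.474 with an estimated correlation). Flavonoid genes were placed lower (0 of 7 called, 2 over the list alone; adjusted p = 0.000972, and adjusted p = 0.559 with an estimated correlation). Root hair and root markers were placed higher (0 of 6 called, 0 over the list alone; adjusted p = 0.0318, and adjusted p = 0.630 with an estimated correlation). The expansin call was lost without 35S::KNAT1 PAC replicate 2 (adjusted p = 0.146) and PAC+GA3 replicate 3 (0.0928). The flavonoid call was lost without PAC replicate 1 (0.0824) and PAC+GA3 replicates 2 (0.0991) and 3 (0.133). The root call was lost without PAC replicates 1, 2 and 3 in turn (0.0696, 0.0721 and 0.0523) and PAC+GA3 replicate 1 (0.452). As in wild type, 0 members of the secondary wall and lignin lists passed over all genes, and here 0 did over each list alone. Organelle genes had a median log2 change of 0.99, with 0 of 102 called.

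With the replicate block, 81 genes were called in 35S::KNAT1 (25 higher, 56 lower), among them 5 GA feedback genes lower and the GA 2-oxidase genes GA2OX6 and GA2OX4 higher, with LDOX lower and GAI higher. With the block within genotype, chosen after the data were seen, there were 155 (64 higher, 91 lower). DESeq2 called 44 genes, and a fit of only these 6 libraries called 37. Leaving out 35S::KNAT1 PAC replicate 2 gave 2 genes and replicate 3 gave 5. Without 35S::KNAT1 PAC+GA3 replicates 1, 2 and 3 in turn there were 8, 6 and 3, and without wild-type PAC replicate 3 there were 12. Without the 3 libraries of high rRNA share there were 9. Of 22 alternatives, ADS1(AT1G06080) was not called in 10, CYP78A5, AGP4 and GASA5 in 8 each, GID1A in 6, CSLB03 in 5, GA20OX2 in 3 and SCL3 in 1, and GA3OX1 and CYP96A12 were called in all.

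**Figure D2:**
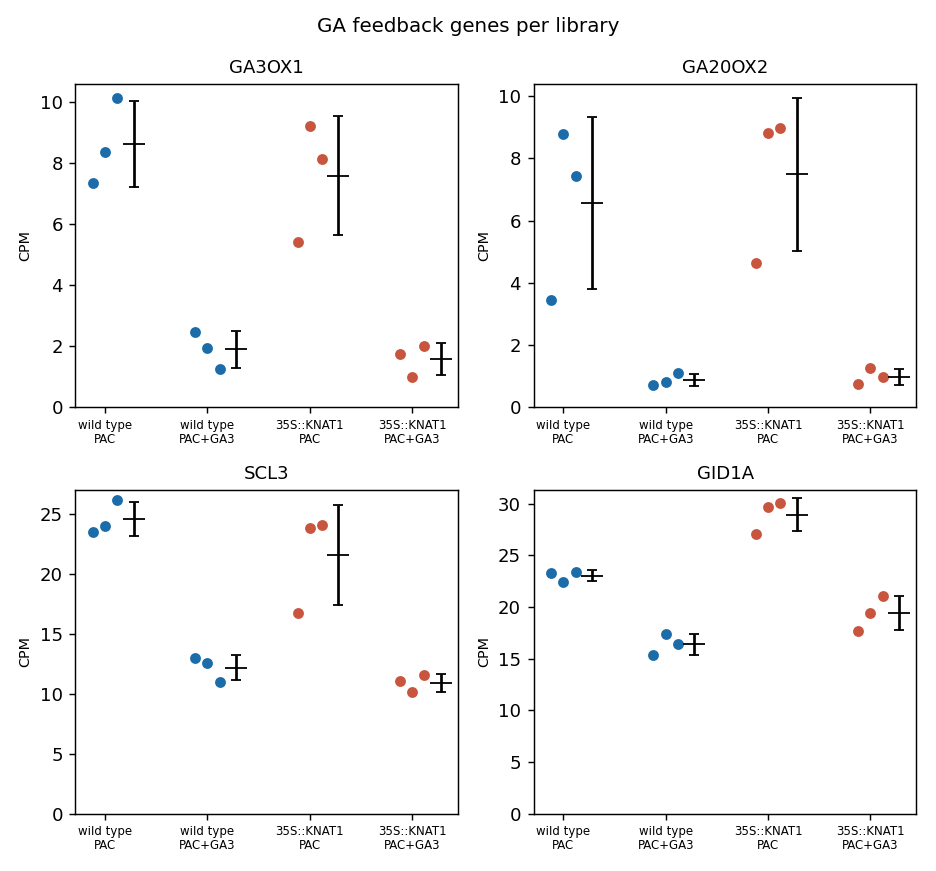
Levels in CPM of GA3OX1, GA20OX2, SCL3 and GID1A in each library, by group, on axes that start at 0; points are libraries, and the bar beside them is the mean with its SD (n = 3). GA3OX1 means lie at 8.64 and 7.60 CPM under PAC and at 1.90 and 1.58 CPM under PAC+GA3 in wild type and 35S::KNAT1.

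Whether the GA effect differed between genotypes was tested as an interaction. No gene passed with edgeR (0 higher, 0 lower), 363 genes had an unadjusted p below 0.05 where 994 would by chance, and DESeq2 also called 0. Small p-values were thus scarcer than chance alone gives, so this test called too rarely. Its 0 calls do not show that the GA effect was the same in both genotypes. Those 363 became 762 without wild-type PAC replicate 1, 573 without wild-type PAC+GA3 replicate 1 and 768 with the block within genotype. With that block, chosen after the data were seen, 3 genes were called, all at an adjusted p of 1 without it: AT2G07687 and the plastid gene PSAI as higher (4.90 ± 0.61 and 3.36 ± 0.50, SE) and AT1G29660 as lower (-0.73 ± 0.11). They are named for their values. Both higher genes stood highest within their group in 35S::KNAT1 PAC+GA3 replicate 1, a library of high organelle share, and organelle genes had a median of 2.60 in the interaction, with 0 of 102 called without the block. PSAI thus moved with the libraries of high organelle share. The GA effect in 35S::KNAT1 minus that in wild type was -0.10 for GA3OX1 (95% interval -1.01 to 0.81), 0.03 for SCL3 (-0.40 to 0.46), -0.03 for GA20OX2 (-1.56 to 1.5) and -0.08 for GID1A (-0.39 to 0.22), on the log2 scale. These intervals do not exclude sizeable differences. Among the 26 genes called in either genotype, the intervals of 5 excluded 0 before any adjustment, all at an edgeR adjusted p of 1. These were CYP78A5 (0.13 to 1.25), AT5G45650 (0.15 to 0.94), CSLB03 (-1.46 to -0.05), GASA5 (-1.53 to -0.01) and XTH32 (-0.59 to -0.03). Each was called in a single genotype and changed more there, which choosing genes by those calls favours. All 26 had the same sign in both genotypes. Libraries of one number deviated together between genotypes under PAC, so the lists of the genotypes were not fully independent. Of the 26, 5 were lower in both, where independent lists would share 0.00573. These 5 were GA20OX2, GA3OX1, SCL3, CAX1 and AT1G33790. Across all genes, which are not independent replicates, the GA effects correlated with a Pearson r of 0.125 and a Spearman rho of 0.349. This r depended on libraries and genes: it was 0.053 without 35S::KNAT1 PAC replicate 2, 0.256 and 0.059 without 35S::KNAT1 PAC+GA3 replicates 1 and 3, 0.024 with no filter, 0.274 without rRNA and organelle genes and 0.217 without the 3 libraries of high rRNA share. Of the gene lists, camera called auxin response for the interaction, a call lost with an estimated correlation (0 of 21 members called, 0 adjusted over the list alone, median -0.46, camera adjusted p = 0.000305, and adjusted p = 0.630 with an estimated correlation). GA catabolism had no camera call (adjusted p = 0.154), but 1 of its 4 tested members was higher adjusted over the list alone. Its member GA2OX4 differed by 3.07 ± 1.02 (SE), with only 4 counts in 35S::KNAT1 under PAC.

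The genotype comparison under PAC asked what differed between the KNAT1 overexpression line and wild type when GA synthesis was blocked. Whole seedlings of the lines were compared. Effects of KNAT1 overexpression, of line background and of tissue proportions therefore cannot be told apart by the genotype calls in either medium. Of the organ boundary genes, 4 rose: LOB by 1.31 ± 0.21 (SE) on the log2 scale, CUC1 by 1.85 ± 0.43, BOP1 by 0.84 ± 0.26 and BOP2 by 0.60 ± 0.11. CUC2 and CUC3 did not pass (-0.86 ± 0.49 and -0.43 ± 0.42, at adjusted p of 0.224 and 0.513). The KNOX genes STM and KNAT6, related to KNAT1 and active in meristems, fell by 1.38 and 0.76 on the log2 scale, with SEs of 0.33 and 0.20. Several wall-loosening and auxin genes fell. EXPB3 changed by -1.63 ± 0.11, XTH20 by -1.72 ± 0.13, EXPA15 by -1.25 ± 0.12 and the auxin repressor gene IAA29 by -2.67 ± 0.25 (SE). The photosynthetic genes RBCS1A and CAB1 fell by 0.97 and 0.90 on the log2 scale, with SEs of 0.12 and 0.14.

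In total 2443 genes were higher and 2574 lower in 35S::KNAT1 under PAC (edgeR adjusted p below 0.05), and 1439 of the 5017 changed at least 2-fold. These calls were 25.24% of all genes tested, so a list with about that share called does not stand out by its count. The higher genes made up 48.7% of the calls. Scaling to total counts alone moved the median of all genes to 0.10 and that share to 67.4%, so directions hold relative to the scaling. Of the 15 tested KNOX, BELL and boundary genes, KNAT1 included, 7 rose, 2 fell and 6 did not pass, with no camera call (adjusted p = 0.154; adjusted p = 0.630 with an estimated correlation). Lignin synthesis had 8 of 20 members lower and 0 higher, 9 lower adjusted over the list alone, and a camera call as lower (adjusted p = 0.00482; adjusted p = 0.559 with an estimated correlation). PAL4, a phenylalanine ammonia-lyase, changed by -0.89 ± 0.12 (SE), the laccase genes IRX12 and LAC17 by -0.42 ± 0.11 and -0.45 ± 0.13, and HCT by -0.28 ± 0.08. Of 15 tested secondary wall transcription factors, MYB20 fell (-0.89 ± 0.26, SE) and 14 did not pass. The other 12 fixed members, NST1, NST2 and NST3 (the last 2 listed as NAC066 and NAC012) among them, were below the filter. Xylan genes IRX15-L and IRX9 fell, 2 of 11, and 0 of 7 secondary wall cellulose genes passed. With the replicate block 3 cellulose genes and 2 of the transcription factors fell. MYB20 was not called in 4 of 22 alternatives. Green tissue markers had 5 of 10 lower and 1 higher, with a camera call as lower (adjusted p = 0.00316; adjusted p = 0.559 with an estimated correlation). CAB1 and CAB2 are near-identical neighbours, so their separate values are uncertain. GA genes went both ways: the kaurene synthase gene GA2 rose by 0.80 ± 0.10 (SE), and GAI, a DELLA gene, and GA2OX6 changed by -0.64 ± 0.09 and -0.75 ± 0.19. Without the 3 libraries of high rRNA share the count was 2577, with wild-type PAC at 1 library. Organelle genes had a median log2 difference of -2.06, with 8 of 102 lower.

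Under PAC the remaining lists had no camera call. The brassinosteroid, cell cycle, cytokinin and vessel cell death counts did not exceed the 25.24% of all tested genes that were called. Expansins and XTHs had 4 of 23 higher and 8 lower (6 and 10 adjusted over the list alone), and auxin response had 2 of 21 higher and 6 lower (2 and 7 over the list alone). GID1A rose and GID1B, XERICO and IQD22 fell among the 12 GA feedback genes, GA2OX6 and GA2OX4 fell among the 4 GA catabolism genes, and of 9 GA early synthesis and DELLA genes 1 rose and 2 fell (2 higher and 2 lower with the replicate block). Of the 7 flavonoid genes, TT5, F3H, DFR and LDOX fell. Of 9 low-oxygen genes 3 rose, AT4G33070, ERF73 and ERF71 (5 with the replicate block), and EXPA7 and NRT2:1 rose among the 6 root markers (4 with the block). Of 9 jasmonate genes VSP2 and AOC1 rose and VSP1 and LOX2 fell, and PR5 fell of the 2 salicylate genes. Of 15 growth bHLH factors PIL5 rose and KDR, PIL1 and BEE1 fell (2 higher and 8 lower with the block). ROT3 rose and BAS1 fell of 9 brassinosteroid genes (2 higher and 1 lower with the block), KRP2 rose and SIM fell of 10 cell cycle genes (1 higher and 2 lower with the block), CKX5 fell of 15 cytokinin genes (1 higher and 2 lower with the block), and XCP1 rose of 7 vessel cell death genes (1 higher and 1 lower with the block). NRT2:1 (adjusted p = 0.0441) was not called in 12 of 21 alternatives, GA2OX4 in 10 of 20 and AT4G33070 in 9 of 22.

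The largest differences came from genes that were near silent in one genotype. SADHU3-1, a retroelement gene (AT3G44042, chromosome 3, 15813075 to 15814056), had 0 counts in wild type and 846 in 35S::KNAT1 under PAC, at least 91.5-fold higher at a floor of 3 counts per library. SADHU3-2 was at least 126-fold higher on the same floor. SADHU genes are a repeated family, so reads may be shared between copies. HSD2 had 1 count in wild type and 1575 in 35S::KNAT1, at least 170-fold higher on that floor. The ratio of its counts without the floor was 1530 (95% exact counting interval 275 to 60600). CRU3, a seed storage protein gene (AT4G28520, chromosome 4, 14087556 to 14089796), had 1249 counts in wild type and 0 in 35S::KNAT1, at least 143-fold lower. CRU3 varied widely in wild type, at 38.0 ± 20.9 CPM (SD, n = 3), and was not called in 7 of 22 alternatives. PER1, emb2204, OLEO1, CYP705A13 and OLEO2 also had 0 counts there and were at least 27.4-, 22.0-, 21.9-, 21.0- and 19.2-fold lower. Floors and intervals cover counting error only.

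The genotype comparison was repeated under PAC+GA3. LOB stood 1.37 ± 0.20 (SE) higher in 35S::KNAT1, CUC1 2.04 ± 0.41 and the BELL gene RPL 0.77 ± 0.15, on the log2 scale. STM changed by -1.22 ± 0.34 and KNAT6 by -1.02 ± 0.20. The auxin-responsive genes IAA29, IAA1 and IAA2 fell by 2.14, 1.07 and 0.81 on the log2 scale, with SEs of 0.22, 0.18 and 0.10. PRE1, a growth-promoting bHLH gene, changed by -2.11 ± 0.46 (SE), and the cytokinin response regulator gene ARR7 by -0.87 ± 0.19.

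Here 2382 genes were higher and 2695 lower (edgeR adjusted p below 0.05), 1429 of them at least 2-fold. All calls made up 25.54% of the genes tested, and the lignin count below did not exceed that share. Higher genes made up 46.9% of calls, and 66.5% when scaled to total counts alone, which moved the median of all genes to 0.12. Auxin response had 10 of 21 members lower and 2 higher (11 and 2 adjusted over the list alone), with a camera call as lower (adjusted p = 0.00118; adjusted p = 0.695 with an estimated correlation). Expansins and XTHs had 11 of 23 lower and 3 higher, 11 and 5 adjusted over the list alone, and a call as lower (adjusted p = 0.0240; adjusted p = 0.546 with an estimated correlation). Lignin synthesis had 4 of 20 lower, 3 adjusted over the list alone, and a call as lower (adjusted p = 0.00680; adjusted p = 0.576 with an estimated correlation). Green tissue markers had 7 of 10 lower and 1 higher, the same counts adjusted over the list alone, and a call as lower (adjusted p = 0.00178; adjusted p = 0.559 with an estimated correlation). KNOX, BELL and boundary genes again had 7 higher and 2 lower of 15, 8 and 2 adjusted over the list alone, without a camera call (adjusted p = 0.0572; adjusted p = 0.559 with an estimated correlation). MYB20 was the secondary wall transcription factor that fell, by 0.77 on the log2 scale with an SE of 0.25 (0 adjusted over the list alone), and IRX15-L and CTL2 were the xylan and cellulose genes that fell. MYB20 was not called in 7 of 22 alternatives. SADHU3-1 was at least 103-fold higher and CRU3 at least 143-fold lower, at the same floor. Organelle genes had a median log2 difference of 0.56, with 1 of 102 higher.

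Under PAC+GA3 the other lists had no camera call. The GA feedback, GA catabolism, low-oxygen, brassinosteroid and cytokinin counts did not exceed the 25.54% of all tested genes that were called. GID1B, XERICO and IQD22 fell among the GA feedback genes, GA2OX6 fell among the GA catabolism genes, and GA2 and CYP88A3 rose and GAI fell among the GA early synthesis and DELLA genes. TT5, DFR and LDOX fell among the flavonoid genes, HB1 rose among the low-oxygen genes, and EXPA7 and NRT2:1 rose and PIP2;4 fell among the root markers. AOC1 rose and VSP1, LOX2 and JAZ10 fell among the jasmonate genes, and PR5 fell of the salicylate pair. Among growth bHLH factors PIL5 rose and 6 fell, among them KDR and HFR1. DET2 rose among the brassinosteroid genes, KRP2 rose and SIM and CYCD3;1 fell among the cell cycle genes, ARR7, RR3 and CKX6 fell among the cytokinin genes, and XCP1 rose and RIP3 fell among the vessel cell death genes. DET2 (adjusted p = 0.0494) was not called in 17 of 22 alternatives, and 0 brassinosteroid and 0 low-oxygen genes passed adjusted over the list alone, so the calls of DET2 and HB1 were lost there. NRT2:1, at an adjusted p just below 0.05, was not called in 14 of 21 alternatives, RIP3 in 10 of 22, and XCP1 and PIP2;4 in 9 of 22 each.

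The genotype effect was compared between media, in pairs of groups that share no library. Across genes, which are not independent replicates, its log2 changes correlated with a Pearson r of 0.944 and a Spearman rho of 0.810. Both media shared 1817 higher genes and 2049 lower genes, where independent lists would share 293 and 349, and 99.0% of the 6228 genes called in either medium had the same sign in both. The 2 comparisons were not fully independent, since libraries of one number deviated together between media within each genotype. Any fixed difference between the lines would also recur in both media.

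**Figure D3:**
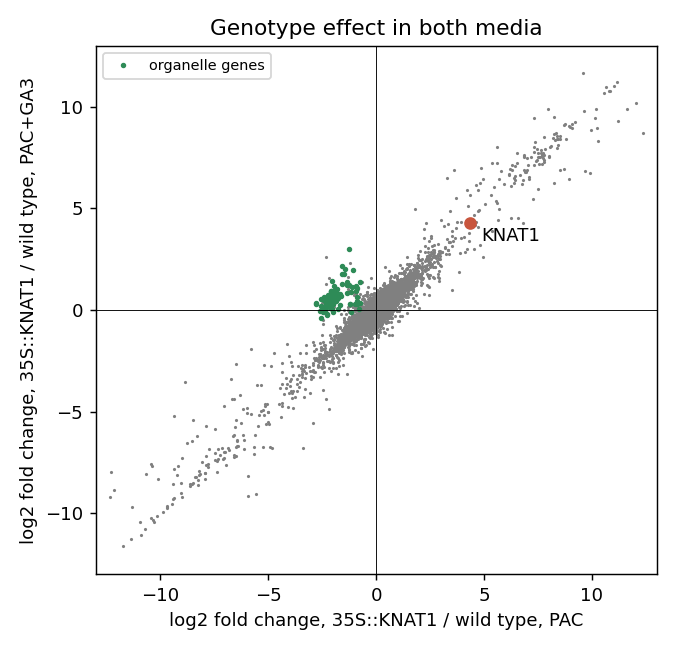
Log2 fold change of 35S::KNAT1 against wild type under PAC (x axis) and under PAC+GA3 (y axis) for the 19879 genes tested; each point is a gene, with KNAT1 marked and the 102 organelle genes in green. Most points follow the diagonal (Pearson r of 0.944 across genes), while a group made up largely of organelle genes lies off it, with organelle medians of -2.06 under PAC and 0.56 under PAC+GA3.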

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

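The tests of silent genes and seed genes below, and the fit without rRNA and organelle genes, were chosen after the results had been seen. Camera called the auxin response list for the interaction (adjusted p = 0.000305), but not with an estimated correlation (adjusted p = 0.630). Fry, which tests against no change, gave an adjusted p of 0.554, and 0 of the list's 21 members passed alone. Over fits that each left out a library the camera value ranged from 1.15e-06 to 0.0443. The list stood out because the difference between genotypes was itself tested.

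In total 115 genes had at most 3 counts in every library of one genotype and at least 2 CPM in every library of the other, 59 silent in wild type and 56 silent in 35S::KNAT1. A few introgressed chromosome segments would place them in a few regions. They fell in 63 different 1-Mb windows on 5 chromosomes, of 123 windows with expressed genes, which argues against a few segments as the source of all. Some did lie in runs, such as AT3G60950, AT3G60960 and AT3G60980, silent in 35S::KNAT1, and AT5G46490, AT5G46510 and AT5G46520, silent in wild type. A local segment behind such runs was not tested. A difference in genetic background between the lines is a candidate explanation. Pseudogenes and non-coding loci made up 32.2% of the silent genes and 2.3% of the other genes called in both media (odds ratio 20.5, 95% interval 12.7 to 32.8, Fisher's exact test, two-sided). These sets were not matched on expression level, and a weakly expressed gene falls to 3 counts more easily. The ratio thus cannot tell a background difference from an effect of KNAT1 overexpression. The labels give both genotypes the same accession. An effect of KNAT1 overexpression on these genes was not tested apart from the background and stays open, and so does the part of all 5017 and 5077 genotype calls that such a difference may account for.

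Seed maturation genes were present in wild-type libraries and nearly absent from 35S::KNAT1, with CRA1 at 2709 counts against 16 and CRU3 at 2527 against 0. Whole mature seeds mixed into the wild-type samples would bring the other storage protein transcripts too. Of the 7 such genes beside CRA1, 5 (CRU2, SESA2, SESA3, SESA4 and SESA5, not CRU3 and SESA1) stood below a hundredth of its wild-type counts. This argues against whole mature seeds, although 12 of the 17 seed genes listed had more than 18 counts there. CRA1 and CRU3 also varied together over the wild-type libraries, from 163 to 706 and from 143 to 782 counts. Other seed material in varying amounts was thus not excluded. The seed genes did not all vary in one proportion, however. In wild type PER1 had 88, 50 and 102 counts under PAC and 41, 10 and 37 under PAC+GA3. OLEO2, EM6 and ABI3 were also lower with GA3 without overlap, while the other detected seed genes, CRA1 and CRU3 among them, overlapped. These seed genes were not among those called for GA3 in wild type. Independent variants at single loci would make further seed genes near silent no more often than other genes, but of 5 further detected seed genes 3 (SESA1, EM6 and ABI3) had at most 3 counts over the 6 35S::KNAT1 libraries, against 107 of 2963 other genes with like wild-type counts (Fisher's exact test, two-sided, p = 0.000469), which argues against it. The other 2, OLEO4 and TIP3;2, were detected in both genotypes, and all these counts were known when the tests were set. A shared cause, be it KNAT1 overexpression or another difference between the lines, was not tested further and stays open.

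RNA without a poly(A) tail carried over into 3 libraries is a candidate explanation for their high rRNA share. It was not tested, since the 3 libraries were singled out by the same rRNA and organelle values. Of 102 organelle genes tested, 100% were highest in 35S::KNAT1 PAC+GA3 replicate 1 within its group, and 100% were lowest in wild-type PAC replicate 1 within its group. Removing rRNA and organelle genes left 17 GA calls in wild type, against 9 with them. No biological explanation was tested, and the cause stays open.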

How the results depend on the processing

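The fits with a block within genotype, without rRNA and organelle genes and without 3 libraries were chosen after seeing the data. GA calls in wild type were 14 with total counts, 18 with no filter, 43 with DESeq2, 2 in only the groups compared, 94 with the replicate block, 238 with it within genotype, 17 without rRNA and organelle genes and 0 without the 3 libraries. In 35S::KNAT1 they were 44 with DESeq2, 37 in only the groups compared, 81 with the replicate block, 155 with it within genotype and 9 without the 3 libraries. The genotype effect under PAC gave 2577 calls without the 3 libraries, and the interaction 3 with the block within genotype. Leaving out each library gave 3 to 16, 2 to 24, 3858 to 5369, 3984 to 5316 and 0 to 0 calls in the order of the report's comparisons (GA in wild type, GA in 35S::KNAT1, genotype under PAC, genotype under PAC+GA3, interaction), and 5 to 7, 3 to 5, 2 to 4, 4 to 6 and 1 to 4 lists. Lists called fell to 0 in each comparison with an estimated correlation. With the replicate block they were 2 for the interaction. Fry, which asks another question than camera, called 3, 2, 5 and 0 for GA in wild type, GA in 35S::KNAT1, genotype under PAC and the interaction. For GA these were GA feedback and GA catabolism in both genotypes, and expansins and XTHs in wild type. For genotype under PAC they were GA catabolism, KNOX, BELL and boundary genes, lignin synthesis, expansins and XTHs, and green tissue markers. The correlation of GA effects was 0.024 with no filter, 0.274 without rRNA and organelle genes, 0.217 without the 3 libraries and 0.053 to 0.256 leaving out each library. That of genotype effects was 0.801 with no filter, 0.951 with a strict filter, 0.953 with the block within genotype, 0.959 without rRNA and organelle genes, 0.929 without the 3 libraries and 0.924 to 0.949 leaving out each library. The causes were not tested. Of 3295 values of named genes under alternatives, 2973 kept their call, 322 lost it and 0 reversed. Of 272 list values, 240 kept their call, 32 lost it and 0 reversed. For genotype under PAC+GA3 and the interaction, whose libraries the numbers do not all pair, the replicate block gave 6297 and 0 gene calls, against 5077 and 0 without it, and 580 interaction genes at an unadjusted p below 0.05, against 363. For genotype under PAC it gave 6169, against 5017. Under PAC+GA3 it gave 8 lignin genes lower and 4 low-oxygen and 4 root genes higher, against 4, 1 and 2. For the interaction camera then also called the cytokinin list (adjusted p = 0.0405 with the block and 0.0855 without it; with an estimated correlation, adjusted p = 0.425 with the block and 0.670 without it). The block changed no other list call by camera. Among libraries of other groups, each of the 12 deviated most like one of its own number. This stays a hint, since the labels do not say what the shared letter in their titles marks. Low counts keep 12 secondary wall transcription factors untested.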

Other observations

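The contrast, the gene families and the splits described here were chosen after the data had been seen. Averaged over both genotypes, GA3 changed 154 genes (64 higher, 90 lower) at an edgeR adjusted p below 0.05. All had the same sign in each genotype, which selection on the average favours. Of the 154, 128 were called in neither genotype alone. With the replicate block 588 were called, including all 154. Of the GA feedback list 8 of 12 members fell, among them the receptor genes GID1A and GID1B and the RING gene XERICO. Of the 7 tested flavonoid genes, DFR and LDOX fell, by 2.30 ± 0.38 and 2.12 ± 0.29 (SE) on the log2 scale. Outside that list, UF3GT fell by 2.39 ± 0.54 and the glutathione transferase gene GSTF12 by 1.18 ± 0.25. Among the rises were the sugar transporter gene SWEET13 (1.13 ± 0.25), the cytokinin oxidase gene CKX1 (0.79 ± 0.17), GA2OX6 (0.76 ± 0.12), XTH17 (0.72 ± 0.16), EXPA1 (0.61 ± 0.09), the DELLA genes RGL1 (0.60 ± 0.10) and GAI, and the brassinosteroid synthesis gene BR6OX1 (0.60 ± 0.13). Outside the expansin and XTH list, EXPA17 and XTH32 changed by -1.14 ± 0.25 and -0.44 ± 0.06. IPT3, the 1 called member of the cytokinin list, changed by -0.41 ± 0.09. None of the secondary wall, lignin or KNOX lists had a member called. These genes are named because of their values.

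Other families, 186 groups of at least 10 genes with a shared description, were tested with camera in 930 tests. It called 31, and with an estimated correlation 0, where each of the 31 had an adjusted p of 0.994, so none is taken as established. By comparison they were 14 for GA in wild type, 10 for GA in 35S::KNAT1, 1 and 4 for genotype under PAC and PAC+GA3, and 2 for the interaction. With GA3 they included histone genes as higher in wild type (median 0.19, adjusted p = 5.64e-06) and 35S::KNAT1 (median 0.09, adjusted p = 0.0174), and pentatricopeptide and tetratricopeptide repeat genes as lower in both. Between genotypes they included fibrillin genes as lower (adjusted p = 0.0174 under PAC and 0.00545 under PAC+GA3, with 5 and 8 of 10 members lower), and for the interaction SAUR genes as lower (adjusted p = 0.00212).

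The number of genes called was set against other splits of the same libraries. For GA in wild type, 2 of the 10 splits of the 6 libraries called as many genes as the real one (real 9, highest other 10). The split with 10 calls set PAC replicates 2 and 3 and PAC+GA3 replicate 3, the 3 wild-type libraries with the highest organelle shares, against the rest, and 0 of its 10 genes were organelle genes. It parted 1 of the 3 replicate pairs, where the real split parted 3, and the splits that also parted 3 called 0. For GA in 35S::KNAT1, 1 of 10 splits, the real one, called as many (real 22, highest other 1). For genotype under PAC and under PAC+GA3 it was also 1 of 10 (real 5017 and 5077, highest other 0 in both). With 10 splits the share cannot fall below 0.05. For the interaction, 100 of 100 splits drawn from 200 gave at least the 0 genes of the real one. Any split does, so this count says nothing about chance. The highest other called 154, and it is the split that exchanges PAC and PAC+GA3 in 35S::KNAT1 alone, so by construction it tests the GA effect summed over genotypes. It parted all 6 replicate pairs, as the real split did. The next highest called 20.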
